A study of Mus musculus with 33 samples.

How the data were processed

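The series holds 33 samples from mouse hearts, cardiac myocytes and cultured fibroblasts, and the tables of 8 of them were analysed. The labels describe these 8 as cardiac myocytes isolated from the hearts of wild-type (WT) mice and of mice with a knockout (KO) of Rbfox2, on a Black Swiss background. Of these, 2 were measured by 3′-end RNA sequencing (called MAPS in the labels) at 9 weeks of age. The other 6 were measured by RASL-seq at 5, 9 and 18 weeks. In RASL-seq, pairs of DNA probes that meet at a splice junction are ligated on the RNA, amplified and counted, so that each event gives a count for a short and a long isoform. The ChIP-seq, CLIP-seq and GRO-seq samples were not analysed here.

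The labels list 1 sample per genotype and age, while the tables hold 3 numbered columns for each. Columns of a group were compared by the chi-square statistic of their counts per degree of freedom, over features with at least 20 counts. It lay between 5.84 and 64.6 over all pairs of columns within a group, far above the value of 1 that repeat sequencing of a library would give, so the columns were taken as separate libraries. The labels do not say whether these came from separate animals, and the p-values below measure the spread between libraries only.

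For the 3′-end table, the authors deposited a signal per gene in reads scaled to 10000000 per library (RP10M), with 1 decimal, per the file headers. Whole reads were recovered by dividing each column by the value of 1 read. Between 99.7% and 100% of the values came out whole within a tolerance of 0.1, and the columns held 7372791, 5266623 and 9563472 reads for WT and 4007538, 4652038 and 5423441 for KO. The values of WT library 2 sum to 9529443.7 rather than 10000000, and no header or label says why. For the RASL-seq table, the authors deposited raw counts of the short and the long isoform of 3885 events, per the file headers. The submitters' processing notes name cutadapt 1.2.1, Bowtie 0.12.7 and the build mm9 without saying what each was used for. No reference of that build was used here, so no coordinates are given. Gene names are those of the tables. Of 22970 names in the 3′-end table, 20921 (91.1%) matched a current mouse symbol, as did 3276 of the 3885 events. 1 event names no gene and stays without a name. List members were matched by exact name, so members under an older symbol can be missed. The Pb1 and Mtap4 events named below entered no list.

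The design fixed before the data were examined listed a count test for counts and limma for normalised values. Because the 3′-end table holds normalised values, limma 3.58.1 (trend and robust settings, R 4.3.3) on log2(RP10M + 1) was the main test, for 10858 genes with a mean of at least 10 RP10M. Fold changes are on that scale, which understates the change of low genes. Count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0 were alternatives. Gene lists were tested with camera, with a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the lists tested. With 3 libraries per genotype, the estimated version is the weaker test. For the glycolysis list its correlation of -0.0057 lay below the preset 0.01, yet the unadjusted camera p went from 0.00114 to 0.0232. A list that passes only with the preset correlation is therefore not shown to owe this to correlation between genes. Genes that share reads with a near-identical copy are uncertain, since the counting rule for such reads is not stated. Of the genes tested, 75 share all 6 values with another name, 4 of them among the genes that passed the test. The globin genes Hbb-b1 and Hbb-b2 are such a pair.

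For RASL-seq, edgeR's quasi-likelihood test was run on the paired isoform counts, with a term per library and a term for isoform by group, so that it tests the ratio of the isoforms. All 18 libraries entered the same fit. It covered 2032 events of 1650 genes with a mean of at least 20 counts and at least 1 count per isoform. Counts of an event are given per 1000000 counts of the library (CPM). The share of long-isoform counts is given as a percentage. Since probe pairs can ligate with unequal efficiency, this share is not the share of RNA molecules, and it serves to compare groups. Of the events tested, 80 share a count column with another event. Tests passed at a Benjamini-Hochberg adjusted p under 0.05, without a minimum fold. PCR counts without molecular identifiers are not independent molecules.

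Genes to be named were fixed by rule before the data were examined. For the 3′-end data these were Rbfox2, the 10 largest rises and the 10 largest falls among genes that passed with no overlap between genotypes and a mean of at least 100 RP10M, and up to 4 members of each list with the smallest adjusted p. For RASL-seq they were the 10 largest changes in share at each age with a mean of at least 50 counts and no overlap, all events of 17 genes named in advance, and up to 3 events of each of 7 lists. The lists are those whose results stand in the report. Markers of other cell types were included because a myocyte preparation can hold them.

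The alternatives tried were other filters and pseudocounts, other tools and scalings, a minimum change, the replicate number as a block, the compared groups alone and leaving out each library in turn. Alternatives chosen after seeing the data were TMM scaling of the 3′-end values or reads, leaving out RASL-seq libraries with the most Rbfox2 counts or the highest level of other cell types' markers, and that level as a covariate. The marker level of a RASL-seq library is the mean log2 CPM, relative to all libraries, of the 8 events in the fixed fibroblast, endothelial and extracellular matrix lists with a mean of at least 20 counts. They lie in 5 genes (Emcn, Postn, Fn1, Pecam1 and Tgfb2). The splicing shift of a library is its mean log2 ratio change against the WT libraries of its age, in the KO direction, over events that passed at 1 or both of the other ages with the same direction there.

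The scripts were tested on simulated data drawn from the real means, dispersions and library sizes. With 3 libraries per genotype, the 3′-end comparison recovered 1.49% of the genes changed 1.5-fold, 14.9% of those changed 2-fold and 62.1% of those changed 4-fold, among 10781 genes tested. It made 59 calls, of which 7 were false. The week 9 RASL-seq comparison recovered 5.97%, 22.4% and 57.6% of events changed by these folds among 2032 events, with 3 false calls of 60. A simulated week 5 comparison without any change gave 0 calls.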

Results

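Cardiac myocytes of WT and Rbfox2 KO mice were compared by 3′-end RNA sequencing at 9 weeks and by RASL-seq of splice events at 5, 9 and 18 weeks. Rbfox2 encodes an RNA-binding protein that regulates alternative splicing, and the comparisons ask which transcripts and isoforms differ when it is removed. Each group held 3 libraries. The 3′-end libraries held 4007538 to 9563472 recovered reads, and the RASL-seq libraries 1998027 to 12876511 probe counts.

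Rbfox2 itself was lower in every KO library by 3′-end sequencing and by its most counted splice event. By 3′-end sequencing it stood at 278 ± 56.6 RP10M (reads scaled to 10000000 per library) in WT (mean ± SD, n = 3) and 88.5 ± 26.1 in KO, a log2 change of -1.66 (SE 0.30, adjusted p = 0.0233). In RASL-seq, the Rbfox2 event with the most counts (7670) gave 246 ± 56.7, 277 ± 57.3 and 311 ± 24.1 CPM (counts per 1000000) in WT at weeks 5, 9 and 18, against 59.8 ± 29.02, 46.4 ± 31.2 and 27.2 ± 14.9 in KO (n = 3 each). The highest KO library at 93.2 lay below the lowest WT library at 202. A further Rbfox2 event (8783) gave 85.0, 97.2 and 113 CPM in WT and 23.3, 18.8 and 11.4 in KO. The least counted event (8797), near the lower end of the counts, was not lower in every KO library, with 5.99, 3.26 and 4.0 CPM in WT and 4.12, 5.53 and 2.51 in KO. The labels do not say which part of the gene was deleted. A 3′ tag or probe outside the deleted part would not by itself check the genotype, but the 3′ tag and events 7670 and 8783 follow the labels in all libraries, and event 8797 does not. KO week 5 library 3 and KO week 9 library 1, at 93.2 and 82.4, kept the most Rbfox2 counts of their groups.

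**Figure D1:**
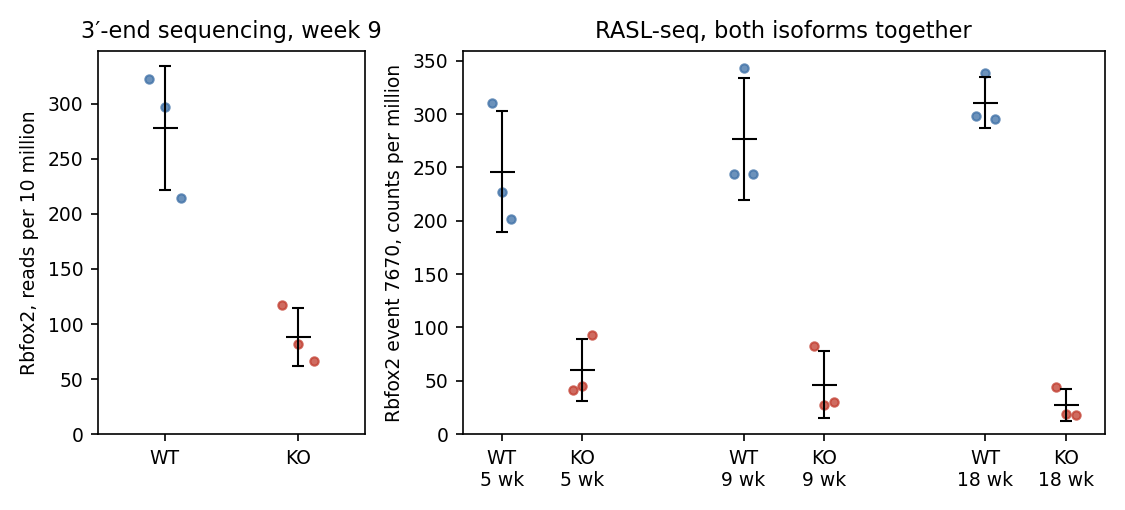
Rbfox2 in each library: RP10M by 3′-end sequencing (left) and CPM of event 7670 by RASL-seq (right). Points are libraries (WT blue, KO red), and bars give the mean ± SD of 3 libraries. Every KO library lies below every WT library, with 93.2 against 202 CPM as the closest RASL-seq pair.

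At 9 weeks, 8 of 17 genes of the fetal and stressed heart and 4 of 22 genes of glycolysis and glucose uptake were higher in KO myocytes, while Myl2, 3 of 23 genes of calcium handling and 3 of 28 genes of the unfolded protein and integrated stress responses were lower. None of these lists stood apart with an estimated correlation, a test with little power at 3 libraries per genotype. Nppa, which encodes atrial natriuretic peptide, rose from 1300 ± 612 to 19850 ± 8315 RP10M (log2 change 4.0, adjusted p = 0.0164). Skeletal actin, Acta1, rose from 1774 ± 877 to 14510 ± 1122 (3.18, adjusted p = 0.0164). Myl2, the ventricular regulatory light chain, fell from 244400 ± 2495 to 138800 ± 10780 (-0.82, adjusted p = 0.00579). Ryr2, the calcium release channel of the sarcoplasmic reticulum, fell from 6898 ± 2433 to 2492 ± 419 (-1.41, adjusted p = 0.0429). Leaving out a single library ended some of these calls. Nppa did not pass without WT library 2, KO library 2 or KO library 3 (adjusted p = 0.0583, 0.0690 and 0.0774), nor Acta1 without KO library 1, 2 or 3 (0.0570, 0.0910 and 0.102), nor Myl2 without KO library 2 or 3 (0.0566 and 0.0695).

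In all, 174 of 10858 genes passed the test, 131 higher and 43 lower in KO, and none of the 174 overlapped between genotypes. Of all genes tested, 23.3% had no overlap, where chance gives 10%. With TMM scaling of the values, chosen after seeing the data, 164 genes passed, 98 higher and 66 lower, and the median log2 change of all genes moved from 0.07 to -0.03. Changes smaller than this shift carry no direction here. DESeq2 gave 450 genes, 246 higher and 204 lower, and the replicate number as a block gave 338, 244 higher and 94 lower. The count rests on few libraries: it was 42 without WT library 2, 420 without WT library 3, 58 without KO library 1 and 18 without KO library 2 or KO library 3. Rbfox2 itself did not pass without WT library 1 (adjusted p = 0.0528), WT library 2 (0.0981), KO library 2 (0.130) or KO library 3 (0.150). Of 46 named genes, 11 passed without each library and under each other alternative that measured them: Psca, Nmrk2, Aqp8, 1700012B15Rik, Ces1d, Syde2, Ano10, Myl4, Pdlim5, Eno1 and Dkk3.

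The 10 largest rises included Psca (log2 change 6.46), Nmrk2 (4.29), Thbs4 (3.68) and Aqp8 (3.58) besides Nppa and Acta1. Nmrk2, a kinase of the NAD synthesis pathway, rose from 80.1 ± 41.8 to 1471 ± 229 RP10M (adjusted p = 0.000621). They also included the atrial light chain Myl7 (3.47), 1700012B15Rik (3.01) and the tropomyosin gene Tpm2 (2.95). The largest falls were those of the carboxylesterase gene Ces1d (-2.84), Ankrd26 (-2.33), Syde2 (-2.29), Ano10 (-2.22), G630090E17Rik (-2.11), Cenpf (-2.02), smooth muscle actin Acta2 (-1.94), Cmya5 (-1.91) and Gpr22 (-1.77). Rbfox1, the paralogue of Rbfox2, completed that list: it fell from 959 ± 228 to 299 ± 73.9 (-1.68, adjusted p = 0.0106). Leaving out KO library 2 or KO library 3 ended the Rbfox1 call (adjusted p = 0.0704 and 0.0824).

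**Figure D2:**
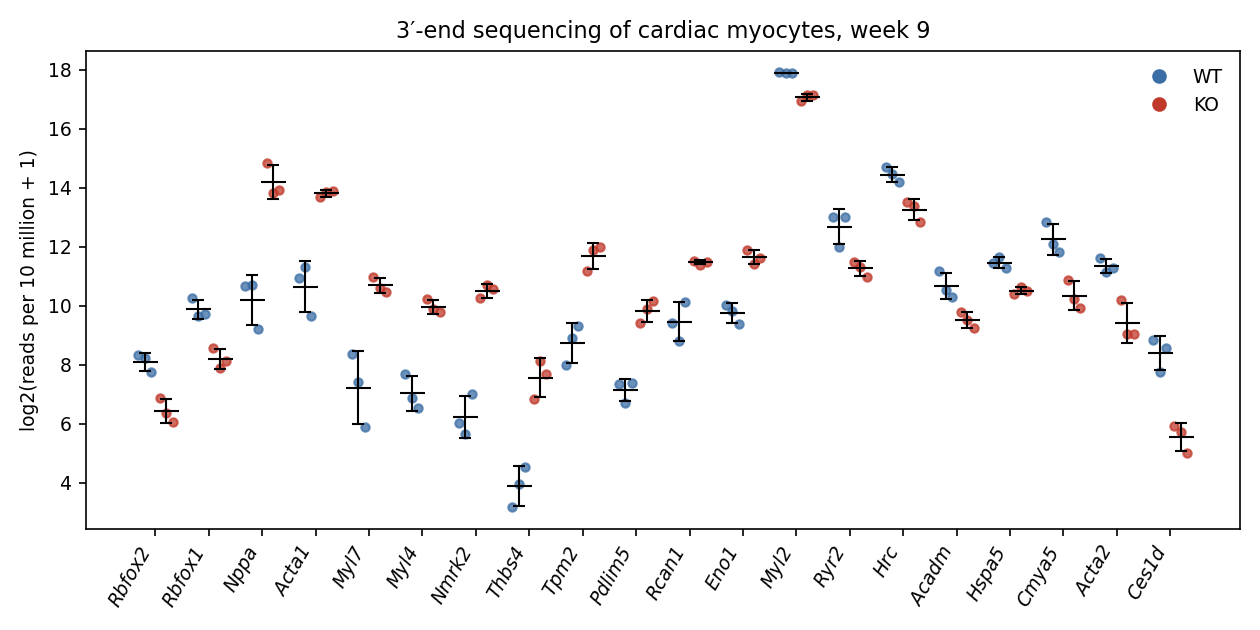
Levels of 20 named genes in the 3′-end libraries at week 9, as log2(RP10M + 1). Points are libraries (WT blue, KO red), and bars give the mean ± SD of the log2 values of 3 libraries. Nppa and Acta1 were higher and Myl2 and Ryr2 lower in all 3 KO libraries.

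Of 17 fetal and stress genes measured, 8 rose, 1 fell and 8 did not pass. Adjusted over the list alone, 12 rose and 1 fell. Besides Nppa, Acta1 and Myl7, these included the atrial light chain Myl4 (log2 change 2.93), filamin C (Flnc, 1.05) and the small heat shock protein gene Hspb7 (1.02), and the fall was that of Acta2. Myl7 did not pass without the filter on low values (adjusted p = 0.0655) or with TMM scaling (0.0584). The list stood above other genes with the preset correlation (adjusted p = 5.51e-11) and did not with an estimated correlation (adjusted p = 0.413). Of 22 genes of glycolysis and glucose uptake, 4 rose, none fell and 18 did not pass, and 10 rose and 1 fell when adjusted over the list alone. Eno1 (1.90), Pfkp (1.77), Gapdh (0.86) and Gpi1 (0.65) rose (list adjusted p = 0.00570, or adjusted p = 0.290 with an estimated correlation). With edgeR, 2 rose with RLE size factors, where Gapdh and Gpi1 did not pass (adjusted p = 0.0577 and 0.103), and 3 with library totals, where Gpi1 did not (0.0563). TMM scaling of the values also left 2. Of 29 genes of fatty acid oxidation, 1 fell and none rose. Adjusted over the list alone, 5 fell and 1 rose. The fall was that of Acadm (-1.14), which did not pass with a pseudocount of 0.1 (adjusted p = 0.0514), and 23 members were lower in KO (list adjusted p = 0.000139, or adjusted p = 0.618 with an estimated correlation). The list mean went from -0.22 to -0.10 without WT library 1. Of 42 genes of oxidative phosphorylation, Cox7a1 fell (-0.56) and none rose, with 1 rise and 1 fall over the list alone (adjusted p = 0.123, but 0.0106 and lower in KO without WT library 3). Cox7a1 did not pass by edgeR with RLE size factors or library totals (adjusted p = 0.0706 and 0.0539).

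Of 24 genes of the adult sarcomere, 2 rose and 2 fell, and 6 rose and 4 fell over the list alone. Pdlim5 (2.68) and Csrp3 (0.66), both of the Z disc, rose, while Myl2 and Cmya5 fell (list adjusted p = 0.921). Csrp3 did not pass by edgeR with RLE size factors or library totals (adjusted p = 0.127 and 0.0784). Myh6, Myh7 and other members of near-identical families carry the uncertainty of shared reads. Of 23 genes of calcium handling, 3 fell and 1 rose, and 4 fell and 1 rose over the list alone. Ryr2, triadin (Trdn, -0.84) and the histidine-rich calcium-binding protein gene Hrc (-1.20) fell, and the calmodulin gene Calm3 rose (1.41). The list as a whole did not stand apart (adjusted p = 0.380), and its median (-0.06) and mean (0.10) differed in sign. The Ryr2 call did not hold without WT library 1, WT library 3 or any of the 3 KO libraries (adjusted p = 0.0755, 0.0569, 0.0858, 0.173 and 0.213). Among 24 ion channels and connexins, 1 rose and none fell, with 1 rise and 1 fall over the list alone (adjusted p = 0.380).

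Of 28 genes of the unfolded protein and integrated stress responses, 3 fell and none rose, and 3 fell and 1 rose over the list alone. These were the chaperone genes Hspa5 (-0.94), Dnajc3 (-1.09) and Canx (-1.24). The list was lower with the preset correlation (adjusted p = 0.0267) and not with an estimated correlation (adjusted p = 0.362). Without WT library 2 or KO library 1 its adjusted p was 0.109 and 0.123. Its mean of -0.11 was -0.20 without WT library 2, -0.02 without WT library 3, -0.04 without KO library 1 and -0.17 without KO library 3. Of 48 splicing regulators, Rbfox1 and Rbfox2 fell and none rose, also over the list alone (adjusted p = 0.0118, or adjusted p = 0.634 with an estimated correlation). The mean of -0.20 was -0.35 without WT library 2 and -0.105 without WT library 3. Of 22 immediate early and hypertrophic signalling genes, 1 rose, Rcan1 (2.02), an inhibitor of calcineurin that is also its target gene. Over the list alone 1 rose and 1 fell, and the list was lower as a whole (adjusted p = 0.0267, or adjusted p = 0.698 with an estimated correlation). It did not pass without WT library 3, KO library 2 or KO library 3 (adjusted p = 0.733, 0.109 and 0.0615), with mean log2 changes of 0.05, -0.18 and -0.24 against -0.30, and its mean was -0.68 without WT library 2 and -0.50 without KO library 1. None of 9 subunits of the polycomb complex PRC2 passed, over all genes or over the list alone (list adjusted p = 0.287). Suz12, a core subunit, stood at 103 ± 25.5 in WT and 44.2 ± 25.1 in KO (adjusted p = 0.153). None of 12 developmental transcription factors of the type bound by polycomb passed (list adjusted p = 0.471), and their median (0.16) and mean (-0.11) differed in sign. None passed among 12 genes of the microRNA pathway (list adjusted p = 0.490), 25 interferon-stimulated genes (0.101) and 22 cell cycle genes (0.609). Over the list alone, 1 interferon-stimulated gene and 1 cell cycle gene rose. The interferon list was lower without WT library 1 (adjusted p = 0.00383) and the cell cycle list higher without WT library 3 (adjusted p = 0.00586). For 0 calls in these groups, limma at an unadjusted p under 0.05 gave 1861 genes over the whole table.

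Single markers of other cell types passed, but with an estimated correlation, the weaker test, none of their lists stood apart. Of 7 atrial myocyte markers, 4 rose (Nppa, Myl4, Myl7 and Dkk3, 3.54), and 6 rose over the list alone. The list stood above other genes (adjusted p = 1.65e-07, or adjusted p = 0.290 with an estimated correlation), and it shares Nppa, Myl4 and Myl7 with the fetal list. Sarcolipin (Sln) had 160, 85 and 1 RP10M in WT and 1078, 778 and 1160 in KO, and did not pass (adjusted p = 0.201). Of 24 genes of the extracellular matrix, Thbs4 rose and 23 were higher in KO, with 4 rises over the list alone. Their median log2 change was 1.42 (adjusted p = 5.85e-07, or adjusted p = 0.618 with an estimated correlation). WT libraries 1, 2 and 3 stood at -1.70, -0.80 and 0.42 and the KO libraries at 0.21, 0.97 and 0.90 against the mean of all libraries, and the mean log2 change of 1.38 was 0.88 without WT library 1. Of 12 fibroblast markers, which share 3 collagen genes with that list, Mfap5 rose (2.18), and 2 rose and 1 fell over the list alone. The fibroblast median was 0.99 (adjusted p = 0.0267, or adjusted p = 0.634 with an estimated correlation), but WT libraries 1, 2 and 3 stood at -1.44, -0.57 and 0.63 against the mean of all libraries. Without WT library 1 the adjusted p of the fibroblast list was 0.262, without KO library 2 it was 0.0843 and without KO library 3 it was 0.0914. The fibroblast mean of 0.92 was 0.43 without WT library 1 and 1.47 without WT library 3, and Mfap5 did not pass by edgeR with library totals (adjusted p = 0.0629). The endothelial median over 17 markers was 0.007, with no call (adjusted p = 0.476, but 0.0463 and lower in KO without WT library 1).

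Of 12 macrophage markers none passed and 11 were higher (adjusted p = 0.0129, or adjusted p = 0.618 with an estimated correlation, 0.0539 without WT library 1 and 0.0828 with a mean of at least 100 RP10M). Its mean log2 change of 0.89 was 1.49 without WT library 3. Of 4 epicardial markers, the keratin gene Krt18 rose (2.96), alone also over the list (adjusted p = 0.0411, or adjusted p = 0.573 with an estimated correlation). Without WT library 1, WT library 2 or KO library 2 that adjusted p was 0.0541, 0.103 and 0.109. Of 13 markers of smooth muscle cells and pericytes, Des rose (0.93) and Acta2 fell, with 2 rises and 1 fall over the list alone (adjusted p = 0.987). Myocytes express Des as well. The 4 erythroid markers gave no call (adjusted p = 0.650), nor did the only Schwann cell marker measured, Gfra3 (adjusted p = 0.987), or the only adipocyte marker, Fabp4 (adjusted p = 0.0986). Adjusted over its list of 1 gene, Fabp4 fell, from 2212 ± 816 to 1242 ± 138. No lymphocyte marker reached the filter.

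Splice events differed widely between KO and WT at all 3 ages. In KO, the share of the long isoform fell steeply in an event of the kinesin gene Kif21a (8747). The share was 85.9% ± 2.44, 92.5% ± 3.11 and 92.6% ± 2.09 of counts in WT at weeks 5, 9 and 18. In KO it was 8.51% ± 4.05, 5.52% ± 2.44 and 4.71% ± 0.400 (n = 3 each). At week 9 the log2 ratio change of this event was -7.92 (adjusted p = 9.46e-12). An event of Enah (4742), which encodes an actin regulator, went from 86.3% ± 1.44 to 7.39% ± 7.66 at week 9. The calcium/calmodulin-dependent kinase gene Camk2d (3972) went from 62.2% ± 3.64 to 6.74% ± 4.04. In the other direction, Sorbs2 (4048), an adaptor of the Z disc and actin, went from 5.51% ± 0.324 to 65.5% ± 9.86, and the splicing regulator Mbnl1 (6972) from 14.9% ± 2.82 to 80.8% ± 7.34.

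Of 2032 events tested, 205 passed at week 5, 343 at week 9 and 395 at week 18. The long isoform was higher in KO in 81, 162 and 220 of them and lower in 124, 181 and 175. The change was at least 10 percentage points in 123, 192 and 248. The genotypes did not overlap in 200, 327 and 390 of the events that passed, while 25.4%, 30.8% and 36.6% of all events tested had no overlap, where chance gives 10%. The count at week 9 was 216 without KO library 2. Nearly all were cassette exons, which made up 1961 of the events tested and 197, 334 and 380 of those that passed.

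**Figure D3:**
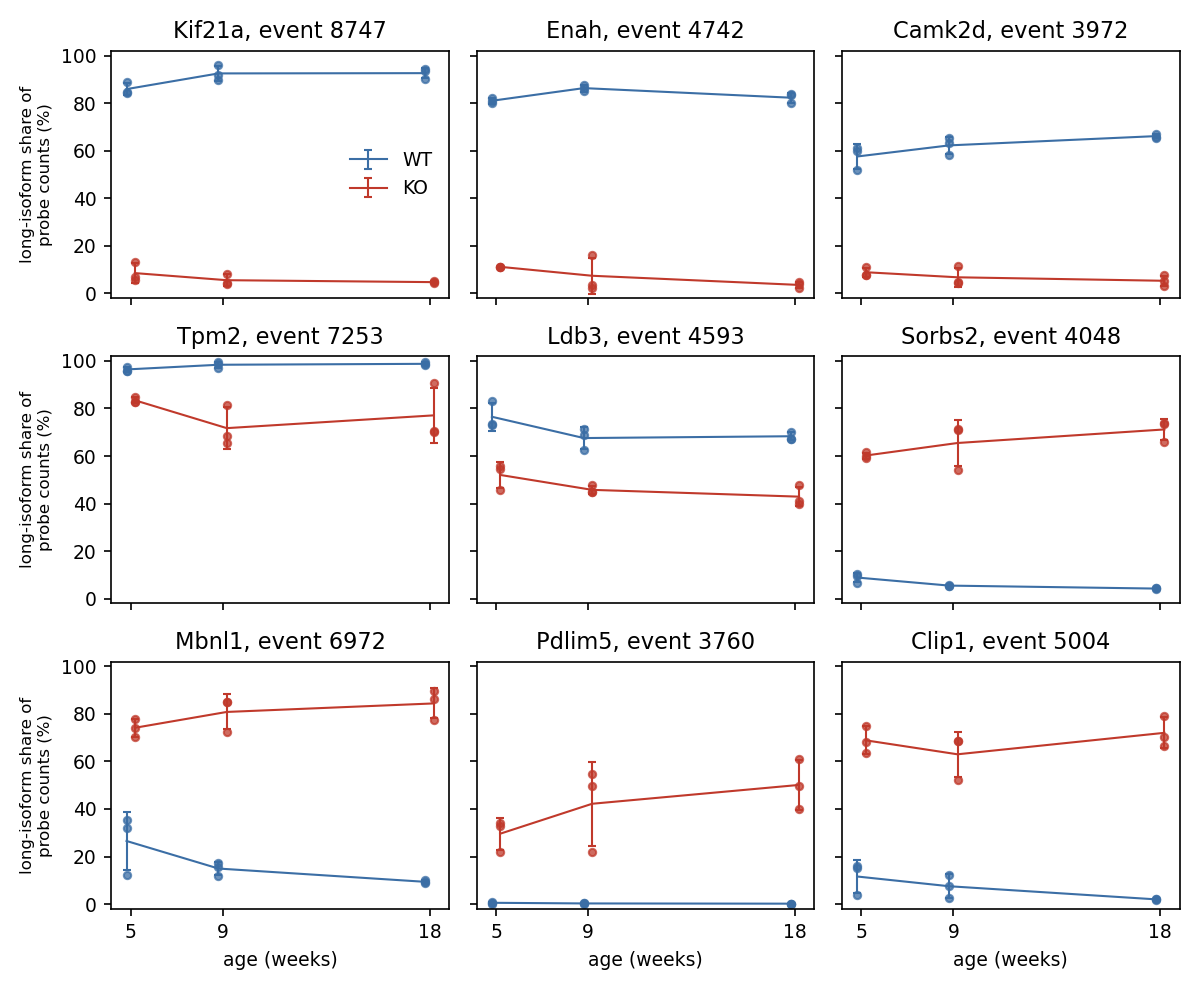
Long-isoform share of probe counts (%) of 9 named events against age in weeks, in WT (blue) and KO (red). Points are libraries, and lines join means with their SD over 3 libraries. Kif21a goes from 92.5% in WT to 5.52% in KO at week 9, and Sorbs2 from 5.51% to 65.5%.

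The largest changes at each age came from a small set of events. Kif21a, Enah, Sorbs2, Camk2d, Mbnl1, Clip1 (5004), 1700012B15Rik (8621) and Lman2l (7161) changed by -77.4, -69.8, 51.3, -48.7, 47.6, 57.3, -47.9 and -47.6 percentage points at week 5. At week 18 these changes were -87.9, -78.7, 66.9, -60.8, 75.02, 70.0, -81.2 and -62.0 points. Usp47 (4185) changed by -48.9 points at week 5. Pb1 (3769) changed by 62.3 and 73.7 points at weeks 9 and 18, and Mtap4 (7683), a microtubule-associated protein gene, by -56.5 and -65.4. An event of Rbm34 (9380) reached the 10 largest at week 18 with -63.7 points. It did not pass at weeks 5 and 9 (adjusted p = 0.407 and 0.0570).

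Events of cytoskeleton genes passed more often than others at each age, and those of sarcomere genes did so less steadily. The 91 cytoskeleton events came from 37 genes and the 15 sarcomere events from 11. Fisher's exact test takes events as independent, so several events of a gene can make p too small, here and for the further lists below. Listed and other events were not matched on counts, so a difference in counts, and with it in power, was not separated from the lists. Of 15 sarcomere and Z-disc events, 6, 10 and 8 passed at weeks 5, 9 and 18 (Fisher's exact test adjusted p = 0.00945, 0.000118 and 0.0119), and 7, 10 and 9 over the list alone. The sarcomere value at week 5 was 0.0986 without WT library 3, 0.0631 without KO library 1, 0.108 without KO library 3 and 0.205 with limma. At week 18 it was 0.0853 with a mean of at least 100 counts. An alternative 3′ splice site of Pdlim5 (3760) rose from 0.270% ± 0.0555 to 42.2% ± 17.6 at week 9, a Tpm2 event (7253) fell from 98.4% ± 1.27 to 71.7% ± 8.71, and a Tpm1 event (7351) rose by 0.484 points. Of 91 events of cytoskeleton and adhesion genes, 29, 35 and 35 passed (exact adjusted p = 7.69e-08, 4.35e-06 and 0.000115), and 33, 42 and 38 over the list alone. Of 21 events of calcium handling and ion channels, 5, 7 and 8 passed (exact adjusted p = 0.101, 0.112 and 0.0978), and 6, 9 and 8 over the list alone. These included Camk2d 9000, with 35.5% ± 2.82 in WT and 3.59% ± 2.71 in KO at week 9, and Camk2g 4824, with 87.1% ± 2.93 and 61.1% ± 10.5.

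Of 34 membrane traffic events, 7, 11 and 13 passed (exact adjusted p = 0.112, 0.0784 and 0.0410), and 9, 11 and 13 over the list alone. At week 18, leaving out WT library 2 or KO library 3 raised that list's adjusted p to 0.0947 and 0.228. It was also 0.0609 with the replicate number as a block, 0.0504 with limma, 0.101 with a mean of at least 100 counts and 0.0708 with the marker covariate. Dnm1l, the dynamin of mitochondrial fission, had an event that rose by 51.6 points (3927) and an event that fell by 29.7 points (4328) at week 9, and Osbpl9 (4642) changed by -33.1. Of 53 events of kinase and GTPase signalling, 11, 14 and 14 passed (exact adjusted p = 0.0458, 0.112 and 0.303), and 14, 16 and 16 over the list alone. The week 5 value was 0.0509 without WT library 2, 0.0839 without KO library 2 and 0.0704 without KO library 3. It was 0.249 with only the libraries compared and 0.0689 with a mean of at least 100 counts. Tsc2 (9129) changed by -44.1, Map3k7 (4367) by 51.8 and Ppp1r12a (4110) by -34.5 points at week 9. The lists of 39 splicing regulator events (6, 7 and 9 passed, also over the list alone; exact adjusted p = 0.363, 0.934 and 0.669) and of 48 transcription and chromatin events (4, 7 and 9 passed, also over the list alone; 1, 0.934 and 1) did not stand apart. Within them, Mbnl2 (4827) rose by 19.8 points, Hnrpdl (8890) by 9.12, Aof2 (4636) by 20.8 and Tcf7l2 (8090) by 23.1, and Bptf (9239) fell by 27.8 points at week 9. At week 18, Hnrpdl and Aof2 changed by -1.55 and -2.13 points and did not pass (adjusted p = 0.605 and 0.811).

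Of the 17 genes named in advance, Mef2d, Ryr2 and Slc8a1 have no event in the table. The Rbfox1 event was not tested, as it missed the filter of at least 1 count per isoform. Ldb3 (4593), a Z-disc gene, changed by -24.5, -21.8 and -25.4 points at weeks 5, 9 and 18 and passed each time. An event of the calcium channel gene Cacna1c (4864) rose by 17.6 points at week 5 and 12.7 at week 18, and a Tpm1 event (9267) by 33.8 points at week 9 and 47.3 at week 18. At week 18 alone, events of Picalm (4928, 17.7 points), Mef2a (9173, -8.77), Fn1 (4406, -5.26), Cacna1c (8805, -0.372) and Ttn (3819, 1.07) passed. An effect that passes at some ages only is not shown to differ between ages. A further Mbnl1 event (3966) changed by -8.95 points at week 5 and -11.3 at week 18, and Ktn1 (3970) by -1.38, -1.62 and -2.30 points at the 3 ages. Ktn1 4491 passed at week 5 (-13.4 points), and Ttn 4680 (-0.111), Enah 7915 (-5.52) and Rbfox2 8797 (20.4 points, on 3.26 and 5.53 CPM in WT and KO) at week 9.

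Many events were shared between ages. Of the events that passed at weeks 9 and 18, 233 passed at both and all 233 moved in the same direction, against 66.7 from independent lists. For weeks 5 and 9 the number was 165, all in the same direction (34.6 from independent lists), and for weeks 5 and 18 it was 169, with 168 in the same direction (39.9). These comparisons use different WT libraries, although they share an estimate of spread. Across events, which are not independent replicates, the log2 changes correlated at r = 0.578 (weeks 5 and 9), 0.571 (weeks 5 and 18) and 0.628 (weeks 9 and 18). In all, 149 events passed at every age, 51 with a higher and 98 with a lower long isoform in KO, and 525 events of 476 genes passed at some age, of which 20, 94 and 142 passed at week 5, 9 or 18 alone.

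**Figure D4:**
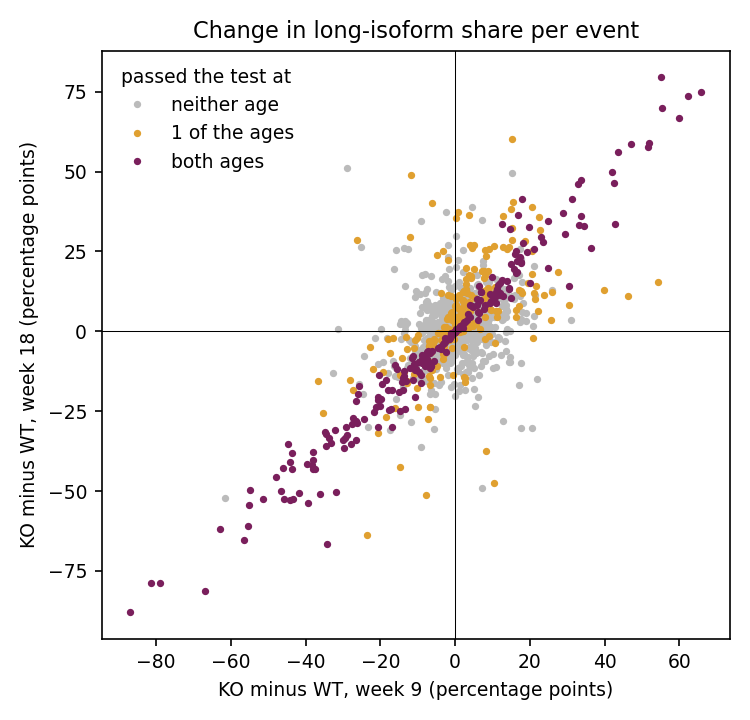
Change in the long-isoform share (KO minus WT, percentage points) of each of 2032 events at week 9 (horizontal) and week 18 (vertical). Purple points passed the test at both ages (233), yellow points at 1 age, grey points at neither. Events that passed at both ages lie in the quadrants of equal sign.

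The KO effect itself differed between week 18 and week 5 in 16 events, among them Sorbs2 4048, Mbnl1 6972, Pb1 3769, Mtap4 7683, Dnm1l 3927 and Rbm34 9380. In Sorbs2, the change grew from 51.3 points at week 5 to 66.9 at week 18 (log2 difference 1.83, adjusted p = 0.0145). In Mbnl1 it grew from 47.6 to 75.02 points (2.64, adjusted p = 0.0432). Of the 16, 11 had a positive and 5 a negative log2 difference, and 247 events had an unadjusted p under 0.05. With limma 7 events passed. With the level of other cell types' markers as a covariate, chosen after seeing the data, 20 passed, 15 of the 16 among them. Another split of these libraries by age, drawn after seeing the data, gave 19 events. It kept the WT ages apart and so still held the WT change with age. The splits therefore neither exclude chance nor show it. The count moved with single libraries: it was 51 without WT week 5 library 1, 9 without WT week 5 library 2 or 3, 4 without WT week 18 library 1, 8 without WT week 18 library 2, 9 without KO week 5 library 3, 4 without KO week 18 library 2 and 6 without KO week 18 library 3.

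In WT myocytes, 115 events differed between week 18 and week 5, with the long isoform higher at week 18 in 71 and lower in 44. The 10 largest were events of Atpbd4 (8658), Ppp3ca (4092), Rbm34 (9380), Ppfibp1 (4382), Vps39 (6968), Mink1 (7069), Tbc1d9b (7190), Vegfa (9369), Atp2b1 (7945) and Dysf (4418). Ppp3ca, a catalytic subunit of calcineurin, had 33.4% ± 11.3 at week 5, 43.9% ± 5.20 at week 9 and 68.1% ± 5.23 at week 18 (adjusted p = 0.00164). Vegfa, an angiogenic factor, had 50.2% ± 10.3, 66.0% ± 4.31 and 75.8% ± 0.216 (adjusted p = 0.000577). Dysf, a gene of membrane repair, had 50.0% ± 9.47, 67.6% ± 3.62 and 74.0% ± 1.51 (adjusted p = 0.00824). Atpbd4 stood at 99.6% ± 0.146 and 99.3% ± 0.0368 at weeks 5 and 9 and at 53.0% ± 2.48 at week 18.

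The mean level of other cell types' markers was lower at later ages in the same libraries, in 7 of the 8 events. The exception, Tgfb2 (8642), had 16.6, 24.9 and 23.4 CPM in WT at week 5 and 24.2, 15.1 and 23.7 at week 18, and 58.0 to 187 in the KO libraries. In WT, the mean marker level was 0.679 at week 5, -0.125 at week 9 and -0.839 at week 18 on the log2 scale. WT week 5 library 1 stood at -0.04, and libraries 2 and 3 at 1.09 and 0.98. The marker level as a covariate, a choice made after seeing the data, gave 6 events in place of 115. Leaving out WT week 5 library 2 or 3 gave 29 and 30 events, leaving out WT week 18 libraries 1, 2 or 3 gave 36, 56 and 48, and leaving out WT week 5 library 1 gave 174. The counts of KO against WT at weeks 5, 9 and 18 were 214, 369 and 395 with the covariate.

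**Figure D5:**
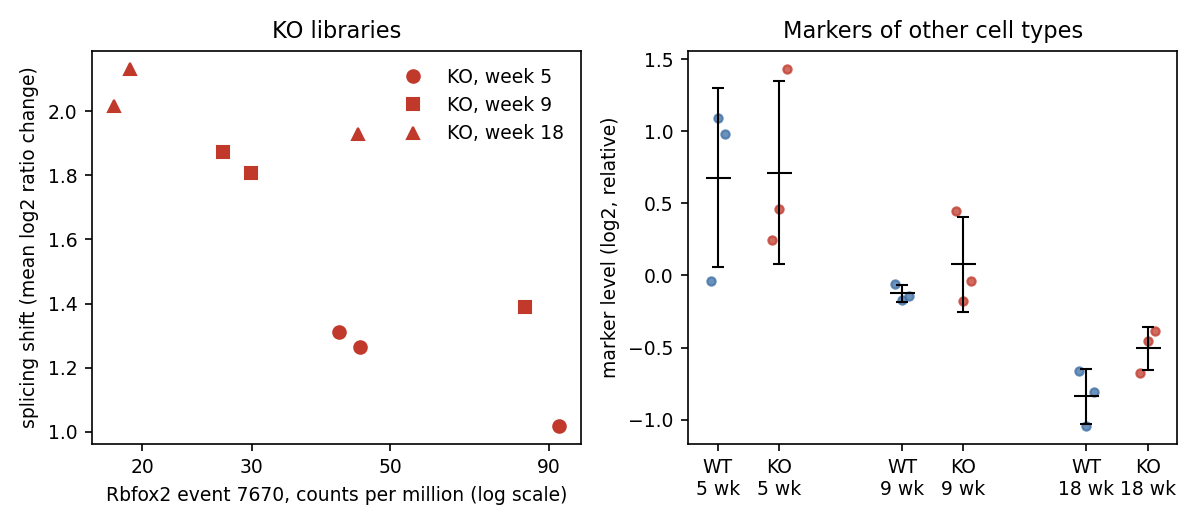
Left: splicing shift of each KO library against its Rbfox2 CPM (event 7670, log scale), by age. The shift is the mean log2 ratio change in the KO direction, over events that passed at 1 or both of the other ages with the same direction there. Right: level of other cell types' markers (mean log2 CPM of 8 events relative to all libraries) per library, with the mean ± SD of 3 libraries (WT blue, KO red), which in WT went from 0.679 at week 5 to -0.839 at week 18.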

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

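In this part, the tests of explanations and of other splits of the libraries were chosen only after the results were seen, while the test of the difference between ages was planned. The KO effect differed between week 18 and week 5 in 16 of 2032 events by that planned test, and this difference between groups is why they are listed here. Of 60 splits of these libraries by age within each genotype, 3 gave at least 16 events, the real one included. The 60 were the real split and others drawn at random from the 200 possible. The highest other split gave 19. Both other splits with at least 16 kept the WT libraries of the 2 ages apart and mixed the KO libraries. They still carried the WT change with age into the comparison, so they do not measure chance alone. The splits therefore neither exclude chance nor show it.

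In 9 events, the change that passed at week 5 was larger in the same direction at week 18. These log2 differences were 3.60 for Pb1 3769, 1.83 for Sorbs2 4048, 1.89 for Phka1 3832, 2.64 for Mbnl1 6972, 1.51 for Nexn 7913, 1.67 for Dnm1l 3927, -3.57 for 1700012B15Rik 8621, -1.59 for Mtap4 7683 and -1.84 for Pb1 4647. Whether the WT or the KO share moved more with age differed between these events. Nexn went from 72.2% to 53.7% in WT and from 84.5% to 87.4% in KO. Mtap4 went from 79.7% to 81.1% in WT and from 34.2% to 15.7% in KO. The log2 differences of Prrc2c 7498, Mll5 8599 and Itga6 7077, which did not pass at week 5, were 2.02, 2.53 and 1.46. In Rbm34 9380 the difference was -6.28, and the WT share of the long isoform was 64.8% at week 5, 46.5% at week 9 and 98.6% at week 18. In Atpbd4 8658 it was 6.35, with 99.6% and 53.0% in WT at weeks 5 and 18, and 93.3% and 88.4% in KO. Smek2 7203 had a difference of 5.07, from 99.5% to 97.8% in WT. Nrap 4390 had a fitted difference of -8.45, which is no bound because the KO libraries had no long-isoform count at week 18 and the share differed by -0.0938 points.

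Among the 9 KO libraries, those with more Rbfox2 counts for their age had a smaller splicing shift. Within ages, log2 Rbfox2 counts and the shift correlated at r = -0.925 (two-sided permutation p = 0.0185, adjusted p = 0.0556 over 3 relations). Without the 2 libraries farthest out in Rbfox2 counts, KO week 9 library 1 and KO week 18 library 1, r was -0.898. With the counts behind the shift thinned to 1998027 per library, r was -0.936, which argues against depth as the source of the differences in shift. The Rbfox2 counts and the choice of events were left at full depth. The adjusted p of the relation misses the threshold. RNA of cells that kept Rbfox2 may account for the relation, but no test apart from the relation itself was run for it. It cannot be told apart from a graded effect of Rbfox2 in myocytes, which was not tested. RNA of other cell types also stays open. The marker level correlated with Rbfox2 counts at r = 0.613 (permutation p = 0.0926) and with the shift at r = -0.744 (permutation p = 0.0741). These r were -0.017 and -0.311 without the 2 libraries farthest out in marker level, KO week 5 library 3 and KO week 9 library 1.

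The 115 events that differed between WT weeks 18 and 5 went with a lower level of other cell types' markers at week 18. Depth is argued against, since all 3 of the WT week 18 totals lay within the range of the week 5 totals. Of the 115 events, 45 did not pass for KO against WT at any age. For these 45, a change was predicted from how each event varied with the marker level among KO libraries of the same age. In KO libraries that level also holds Tgfb2, which followed genotype, so it is not a level of other cell types alone. The WT change correlated with the predicted change at r = 0.59 (one-sided permutation p = 0.0741). Less RNA of other cell types at week 18 may thus be part of the difference and cannot be told apart from age. With the marker level as a covariate, 6 events passed, the median size of the 115 log2 changes went from 1.46 (median SE 0.331) to 1.02 (0.499), and 112 kept their sign. The calls ended through both the smaller change and the larger error, and age itself stays open.

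Several fetal, stress and atrial genes were higher in KO by 3′-end sequencing. Scaling to totals that few genes dominate is argued against, since 7 of the 8 fetal and stress genes that rose still did so with TMM scaling. A lower share of myocytes would by itself lower genes of the cardiomyocyte, whereas the fetal and stress level was higher in every KO library, by at least 0.991 on the log2 scale. That level is the pattern itself, so it cannot decide whether the share of myocytes differed. An earlier test, the fibroblast minus the endothelial level, overlapped between genotypes (gap -0.041) and decided nothing, so a lower share stays open. Atrial cells in the KO preparations may contribute and cannot be told apart from a change within ventricular myocytes: 6 of 7 atrial markers were higher in every KO library, with Clec3b the exception, and 3 of the 7 are fetal genes that stressed ventricular myocytes also express. The fetal response to loss of Rbfox2 stays open as the biological explanation, as untested.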

How the results depend on the processing

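In this part, TMM scaling, the omission of libraries by Rbfox2 counts or marker level, the marker covariate and the other splits were chosen after seeing the data. Among the genes, events and lists counted here no tested direction reversed, but the mean log2 change of the immediate early list went from -0.30 to 0.05 without WT library 3 (adjusted p = 0.733). Of 93 values of the 6 counts under alternatives, 63 stayed within 1.5 times the reported count, 25 were lower and 5 higher. Of 734 values of 46 named genes, 576 kept their direction and side of the threshold and 158 only their direction, and for 951 values of 74 named events these numbers were 898 and 53. For 224 values of 19 gene lists, with direction taken against other genes, they were 192 and 32. Lists that had not passed are not counted, and 6 of them changed direction without 1 library: cell cycle, adult sarcomere, endothelial, smooth muscle and pericyte, erythroid and Schwann cell.

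The 3′-end count of 174 genes was 338 with the replicate number as a block and 450 with DESeq2, and the cause was not tested. Residuals of WT and KO libraries of the same number correlated at 0.279, 0.059 and 0.193, and those of unlike number at -0.243 to 0.123. For each WT library the KO library of the same number gave the highest r, so pairing by number stays open. The main test was planned without a block. A minimum change of 10 percentage points gave 123, 192 and 248 events at weeks 5, 9 and 18 and 55 for WT age, fewer by construction. The difference between ages gave 7 events with limma, and the cause was not tested. Without the 2 WT week 5 libraries with the highest marker level it gave 3 and WT age 5, but this leaves 1 library in that group, assumed to vary like the others, so fewer calls say nothing about marker level. WT age gave 6 with the marker covariate.

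Leaving out 1 library gave 18 to 420 genes by 3′-end sequencing, 156 to 211, 216 to 333 and 310 to 383 events at weeks 5, 9 and 18, 4 to 51 for the difference between ages and 29 to 174 for WT age. Fewer libraries can lower a count, but every such fit left out 1 library and the counts still ranged widely. They depended on which library was left out, and the cause was not tested. With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real and the highest other split gave 174 and 1 genes, and 205 and 1, 343 and 1, 395 and 0, and 115 and 0 events for weeks 5, 9 and 18 and WT age. In each, 1 split, the real one, gave as many. The epicardial list had no gene left at 100 RP10M, and a pseudocount for ratios was not run because counts were deposited. Depth limits genes under 10 RP10M and events under 20 counts.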

Other observations

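The tests of the explanations in this part were chosen only after the results were seen, and the further comparisons of ages were added later too. In KO myocytes, 72 events differed between week 18 and week 5, with the long isoform higher at week 18 in 58 and lower in 14, and 359 had an unadjusted p under 0.05. The level of other cell types' markers was also lower at week 18 in these libraries, at -0.674, -0.458 and -0.385 against 0.244, 0.46 and 1.435 at week 5. Between neighbouring ages in WT few events passed: 5 between weeks 9 and 5 (228 at an unadjusted p under 0.05) and 6 between weeks 18 and 9 (252). The KO effect differed in 4 events between weeks 18 and 9 (180) and by edgeR in 0 between weeks 9 and 5 (160). A Rbfox1 event (8248) missed the filter of at least 1 count per isoform, so its share was not tested. Its counts were 25.1, 35.5 and 49.8 CPM in WT at weeks 5, 9 and 18 and 7.78, 7.13 and 10.2 in KO.

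Genes with a changed splice event might also change in expression. At week 9, 1352 genes were tested by both assays, and 276 had a changed event and 22 a changed level. Both held for 6, against 4.49 from independent lists (odds ratio 1.47, two-sided Fisher's exact p = 0.425), which leaves the question open. They were 1700012B15Rik, Bdh1, Enah, Pdlim5, Rbfox2 and Tpm2. Of these, Rbfox2 is the deleted gene itself, and its changed event (8797) rests on 3.26 and 5.53 CPM in WT and KO.

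KO might move isoform ratios opposite to the change with age. Over 2032 events, the KO effect at week 9 and the WT change from week 5 to week 18 correlated at r = -0.165, and at -0.295 with the marker level as a covariate. Both adjusted changes rest on the same fitted marker slope per event, and an error in it moves them in opposite directions. Part of the step to -0.295 can therefore come from the fit. Of 46 events that passed in both, 36 moved in opposite directions, and of all 115 that passed with WT age, 63 moved opposite to the KO effect, passed or not. Events are not independent, and r without the covariate did not reach the -0.2 set for the test, so this stays open.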
